A study of Methylorubrum extorquens AM1 with 18 samples.

How the data were processed

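Transcript levels were measured in *Methylorubrum extorquens* AM1 with long-oligonucleotide arrays of 10807 spots read in a red and a green channel. Each of 18 arrays compared RNA of stressed with RNA of unstressed cells. The labels give 3 stressors, 3 biological replicates of each and 2 arrays per replicate with the dyes exchanged. Per the labels, 40 ml of a chemostat culture on 25 mM methanol at 28 °C was moved to a flask with the stressor and shaken for 10 min, an untreated sample was moved and shaken likewise, and 5 µg of DNase-treated RNA was labelled from random decamers. No sample taken straight from the chemostat was analysed here. The labels call the replicates biological but do not say that they came from separate chemostat cultures, nor whether arrays shared unstressed RNA.

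Per the file headers, the authors' scans were read with Agilent Feature Extraction 7.5.1, with spatial detrending on, the background-correction setting off and an intensity-dependent dye normalization. The deposited scanner files give mean foreground and median local background signals in units of intensity for both channels, with nothing done to them. They also give processed signals in units of intensity, which the authors' software had detrended and dye-normalized. The deposited log10 ratios are red over green processed signal, held within ±2, and 98.3% of them equal the ratio of the processed signals within 0.001. The deposited flags per spot, another kind of value (0 or 1), mark signals well above background, saturated and non-uniform. The deposited table of the series holds log10 ratios of stressed over unstressed signal. It equals the scanner ratio with its sign turned on arrays whose red channel held unstressed RNA, to within 4.998e-06, and its medians per array lay between −0.0651 and 0.00606. Ratios here were given the same direction, stressed over unstressed.

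The array carries 10153 gene spots, 8022 probes of 60 bases and 7460 genes, of which 7145 have 1 probe, 68 have 2 and 247 have 3. A pair of spots carries each of 2131 probes. Gene identifiers, descriptions and contig positions were taken from the array's own annotation, which names no genome build. None of its identifiers matched the reference table of locus tags, 0 of 7460, so no outside names were used, and 2972 genes have no described product. For 27 probe sequences the same bases serve more than 1 gene, 67 genes in all. A further 11 oligonucleotides, each at 10 spots and without a gene, were left out of the tests. In the 311 genes with several probes the median range between probes was 0.394 log2 units with formaldehyde, 0.330 with hydrogen peroxide and 0.424 with sodium chloride.

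Foreground and background intensities were corrected with limma's normexp method with an offset of 50 and normalized within each array by loess, with control spots at weight 0. Non-uniform spots, 1.05% to 54.0% per array, were left out, and saturated spots, 41 to 151 in red and 14 to 99 in green, were kept. Spots of a probe were averaged. A probe was used when it was well above background in at least 1 channel on at least 6 of 18 arrays, which kept 7968 probes of 7406 genes. Each probe was averaged over both dye orientations of a replicate, or taken from 1 orientation where the other was left out. A gene's probes were then averaged, which gives 1 value per gene and biological replicate. A gene was tested when it had a value in at least 2 replicates of every stressor, a rule chosen after the files had been seen, and 6272 genes were tested and 1134 not. Genes dim in both channels (30, 46 and 18 for formaldehyde, hydrogen peroxide and sodium chloride) or saturated (12, 17 and 35) are given no fold there, and the ratios of those dim in 1 channel (28, 44 and 10) are bounds.

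All replicates entered 1 fit in limma 3.58.1 under R 4.3.3, with a mean for each stressor, 6 residual degrees of freedom and moderated variances (prior degrees of freedom 4.28, prior SD 0.134). Each mean was tested against 0, each pair of means against each other, and all 3 for equality by the moderated F test. Tests were two-sided, p was adjusted by Benjamini-Hochberg over all genes tested, and the threshold was an adjusted p of 0.05. limma's treat was added later to test against a 2-fold change. On simulated data with 50 changed genes of each size among 6272, the formaldehyde test recovered 82% at 0.5 log2 units and 100% at 1, 2 and 3, with 10 unchanged genes called. The difference between formaldehyde and hydrogen peroxide was recovered for 58%, 98%, 100% and 100% of genes, with 8 unchanged genes called.

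Before the data were examined, 20 gene lists, the rule for which genes to name, the tests and most alternatives were fixed. The lists were methanol oxidation, PQQ synthesis, methanopterin (H4MPT) formaldehyde oxidation, formate dehydrogenases, the folate (H4F) branch with the serine cycle, the ethylmalonyl-CoA pathway, polyhydroxybutyrate, chaperones and proteases, peroxide and thiol defence, DNA repair, general stress response, compatible solutes and ion transport, ribosomal proteins, RNA polymerase and translation factors, ATP synthase and NADH dehydrogenase, motility and chemotaxis, iron-sulfur clusters and iron, efflux, cysteine and methionine metabolism, and mobile elements. Members were found by symbol or by words in the description. Symbols were first matched without regard to case, which let unrelated words in, and the match was corrected to the written case after list results had been seen. Lists were tested with limma's camera on 5321 genes with all values, with a preset correlation of 0.01 between genes and again with an estimated correlation, and with fry, and p was adjusted over all 60 tests. A list's p therefore covers only its members with all values, while its counts and median cover all measured members. Members with all values were 24 of 36 ribosomal protein genes, 27 of 36 chaperone and protease genes and 3 of 4 general stress genes. They were 73 of 89 motility genes and 171 of 221 mobile elements. List members were also counted by direction, over all genes and adjusted over the list alone.

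The genes named are, per stressor, the 10 largest rises and falls with a symbol or described product that passed and moved alike in all 3 replicates, leaving out mobile elements, and the 2 largest of any annotation. To these come up to 4 members of each list by smallest adjusted p, the 5 largest differences each way per pair of stressors, and a fixed set of methylotrophy and stress genes wherever measured. Of that set katE, katG, ahpC, phyR, ecfG, otsA and betA carry no name in the array's annotation, and lexA was measured only with non-uniform spots kept. Gene products' known roles are general knowledge and were not measured. Shared responses were measured by correlation across genes and by overlap of calls, against simulated unchanged stressors with common unstressed RNA.

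The alternatives were no background correction, plain subtraction with a floor of 1, the scanner's log ratios, the series table, median centring, scaling between arrays, no filter or a strict filter on dim probes, non-uniform spots kept, the brightest probe of each gene, a variance trend with robust moderation, all 18 arrays with a dye term and the slide as a random block, a replicate block, only the stressors compared in the fit, a 2-fold requirement, and each replicate left out. The slide holds both orientations of 1 replicate, so a slide block and the fit of 18 arrays are the same. Testing with treat, leaving out the non-swapped array of formaldehyde replicate 3, and using only genes read in both orientations were added after the data had been seen. Values came from every array deposited. No genome sequence was used here.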

Results

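*Methylorubrum extorquens* AM1 is a pink-pigmented bacterium that can live on methanol. Methanol carbon passes through formaldehyde, a toxic intermediate that the cell must oxidise or assimilate as fast as it is made. The arrays compared the transcripts of cells given a sudden dose of formaldehyde with those of unstressed cells, and did the same for a peroxide and for a salt dose. Cells from a chemostat on 25 mM methanol at 28 °C were shaken in flasks for 10 min with 15 mM formaldehyde, 100 mM hydrogen peroxide or 5 M sodium chloride, the doses as labelled, and unstressed cells were shaken in flasks for the same time. The labels do not say whether 5 M was a stock or a final concentration. Each stressor had 3 biological replicates, and each replicate was hybridised on a pair of arrays with the dyes exchanged, which makes 6 arrays per stressor and 18 in all. The median signal per array lay between 416 and 1055 in red and between 437 and 935 in green, over a local background of 46 to 51 and 35 to 39. The share of probe spots well above background was 96.6% to 99.1% in red and 98.2% to 99.3% in green. The 2 dye orientations of a replicate correlated at 0.926 to 0.967 across genes, and the replicates of a stressor at 0.936 to 0.946 for formaldehyde, 0.963 to 0.982 for hydrogen peroxide and 0.939 to 0.978 for sodium chloride. Precision was limited by the number of arrays. Below, each value is a mean log2 ratio of stressed to unstressed signal ± SD over 3 replicates unless another n is given, positions are contig, start and end on the array's own annotation, and adjusted p comes from limma. A start above the end marks the reverse strand.

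With formaldehyde 27 of 36 ribosomal protein genes rose and 6 fell, and the list passed in limma's camera with an adjusted p of 1.2e-06 but had an adjusted p = 0.100 with an estimated correlation. When non-uniform spots were kept, 35 of 59 rose and 17 fell. Single genes of the ArsR and TetR families of repressors rose, and genes for katA, a peroxiredoxin, Dps and a glutathione-dependent formaldehyde dehydrogenase fell. The methanopterin route of formaldehyde oxidation had a median ratio of 0.21. Of 6272 genes tested, 4302 changed, 2052 up and 2250 down, and 916 of these changed at least 2-fold, 502 up and 414 down. Loess sets the centre of each array's ratios near 0, so rises and falls are relative to that centre. Under median centring 2190 of 3965 changed genes were up, a share of 55.2% where it was 47.7% here. This comparison addresses what the cell transcribes in the first minutes of an excess of its own intermediate.

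The largest rise with formaldehyde was in a gene for ribosomal protein S12P, RMQ04459 (contig 947, 1 to 147), at 4.34 ± 0.21 with an adjusted p of 2.2e-09. An ArsR family regulator, RMQ09866 (contig 1506, 14863 to 15222), was the next largest of the genes read in all 3 replicates, at 4.01 ± 0.43 with an adjusted p of 6.2e-09. Transposase RMQ07338 (contig 1444, 983 to 1996), named after its value was seen, lay between them at 4.31 ± 0.03 (n = 2). ArsR proteins are small repressors that usually release DNA when a metal or metalloid binds them. Ribosomal protein genes made up most of the remaining top rises, with S6P RMQ02526 (contig 1516, 16147 to 15632) at 3.92 ± 0.22, S1P RMQ01212 (contig 1390, 4760 to 6469) at 3.69 ± 0.15, L33P RMQ11517 (contig 1328, 8190 to 8354) at 3.63 ± 0.29 and L28P RMQ05738 (contig 1351, 2665 to 2967) at 3.49 ± 0.16. L34P RMQ04657 (contig 1436, 16161 to 15868) rose by 3.32 ± 0.30, and another S12P entry, RMQ00454 (contig 1019, 196 to 14), rose by 3.30 ± 0.06. A gene annotated as subunit A of a tungsten formylmethanofuran dehydrogenase, RMQ10663 (contig 512, 440 to 3), a relative of the complex that releases formate from the methanopterin route, rose by 3.23 ± 0.45. The TetR family regulator RMQ02230 (contig 1497, 5707 to 6306), of a family that often represses efflux or detoxification genes, rose by 3.10 ± 0.31.

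The deepest fall of a described gene with formaldehyde was in ybiS, RMQ00690 (contig 1567, 47588 to 46920), a precursor of a periplasmic protein of the L,D-transpeptidase family that ties lipoprotein to the cell wall, at −4.89 ± 0.42 and an adjusted p of 2.2e-07. A catalase fragment, RMQ10649 (contig 475, 531 to 1), followed at −4.30 ± 0.22, and katA, RMQ09549 (contig 1531, 13908 to 15584), stood at −3.63 ± 0.33. Catalases split hydrogen peroxide into water and oxygen. A peroxiredoxin, RMQ03709 (contig 1447, 2348 to 3148), which reduces peroxides through a thiol, fell by 4.10 ± 0.66. Among the other deep falls were yciF RMQ10020 (contig 1547, 30464 to 29964), a stress-induced ferritin-like protein in other bacteria, at −4.04 ± 0.30, and a transglycosylase-associated protein, RMQ12224 (contig 1487, 8624 to 8959), at −3.61 ± 0.18. The unstressed signal of RMQ12224 was 15.9 log2 units with formaldehyde, near the top of the range, so the size of its fall is uncertain. The flagellar rod gene flgC, RMQ05513 (contig 1357, 3332 to 2919), lay at −3.97 ± 0.28, and topoisomerase I, RMQ08276 (contig 1486, 1617 to 2894), which relaxes supercoiled DNA, lay at −3.79 ± 0.55. The glutathione-dependent formaldehyde dehydrogenase gene, RMQ06757 (contig 1250, 3598 to 2369), whose product oxidises formaldehyde bound to glutathione in many bacteria, stood at −3.34 ± 0.31 with an adjusted p of 9.2e-08. An ethanolamine permease gene, RMQ04816 (contig 1384, 62 to 1030), was at −3.27 ± 0.18. Of any annotation, RMQ08196 (contig 1556, 18832 to 18473), with no described product, was the second deepest at −4.47 ± 0.14.

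Genes of methanol and formaldehyde metabolism moved both ways. Of 26 genes of methanol oxidation, 12 rose and 8 fell with formaldehyde, and 12 and 9 when adjusted over the list alone, with a median of 0.16 and a camera adjusted p of 0.231. Within this list mxaS, RMQ04144, of the methanol dehydrogenase assembly cluster, rose by 1.07 ± 0.14, and mxaR, RMQ04256, rose by 0.92 ± 0.09. The sensor kinase gene mxcQ, RMQ07691, which takes part in switching on methanol oxidation, fell by 1.36 ± 0.13. The large subunit of methanol dehydrogenase, mxaF RMQ05966, had a saturated unstressed signal with formaldehyde, so no ratio is read from it there. Its homologue mxaF-prime, RMQ05554, stood at −0.32 ± 0.17 with an adjusted p of 0.00538. Of 7 genes of synthesis of PQQ, the cofactor of methanol dehydrogenase, 4 rose and 1 fell, the same counts adjusted over the list alone, and pqqB, RMQ08765, was highest at 1.67 ± 0.14. The PQQ list had an adjusted p of 0.219.

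Of 23 genes of the methanopterin route, which oxidises formaldehyde to formate, 10 rose and 2 fell with formaldehyde, and 9 and 2 when adjusted over the list alone, with a median of 0.21 and an adjusted p of 0.193. The formaldehyde-activating enzyme gene fae, RMQ09682, which makes the first step of that route fast, rose by 0.52 ± 0.15 with an adjusted p of 8.1e-05. The stressed signal of fae was 16.1 log2 units with formaldehyde, near the top of the range, so the size of its rise is uncertain. Under median centring in place of loess the rise of fae was 0.17 with an adjusted p of 0.128. The dehydrogenase gene mtdB, RMQ05675, stood at 0.06 ± 0.21 and the cyclohydrolase gene mch, RMQ05670, at −0.02 ± 0.20, neither past the threshold. In the formyltransferase complex, fhcB, RMQ00778, rose by 1.11 ± 0.23 while fhcA, RMQ00777, stood at 0.23 ± 0.29 with an adjusted p of 0.0800. Cofactor synthesis genes orf21, RMQ09678, and orf19, RMQ01238, rose by 0.84 ± 0.13 and 0.67 ± 0.11. Formate dehydrogenases, which take the last step to carbon dioxide, split evenly, with 6 of 14 up and 5 down, the same counts adjusted over the list alone and an adjusted p of 0.979. The gamma subunit fdh2C, RMQ04236, rose by 2.04 ± 0.19, whereas a formate dehydrogenase alpha chain, RMQ05881, stood at −1.65 ± 0.12 and fdh3A, RMQ08958, at −1.11 ± 0.17. The beta subunit fdh2B, RMQ12670, averaged 1.39 ± 0.16 over its probes, but the brightest of them gave −0.52.

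On the assimilation side, 4 of 13 genes of the serine cycle and its folate branch rose with formaldehyde and 2 fell, the same when adjusted over the list alone, with an adjusted p of 0.882. The malate dehydrogenase gene mdh, RMQ06488, fell by 1.66 ± 0.24, while sga, RMQ12088, the aminotransferase that turns serine to hydroxypyruvate, rose by 1.08 ± 0.37. Serine hydroxymethyltransferase, glyA RMQ07918, rose by 0.49 ± 0.33, a call lost under median centring at 0.23 and an adjusted p of 0.113. The gene mtdA, RMQ03311, stood at 0.49 ± 0.39 with an adjusted p of 0.0539. Of 16 genes of the ethylmalonyl-CoA pathway, which regenerates glyoxylate for the serine cycle, 1 rose and 2 fell, the same adjusted over the list alone, with an adjusted p of 0.882. The gene pccA, RMQ11711, rose by 0.92 ± 0.22 and the ketothiolase gene phaA, RMQ11702, fell by 0.82 ± 0.19. Of 9 genes of polyhydroxybutyrate metabolism, the cell's carbon store, 4 rose and 4 fell by either adjustment, that is also adjusted over the list alone, with an adjusted p of 0.831. The polymer synthase gene, RMQ06009, fell to −2.52 ± 0.13, the depolymerase gene depB, RMQ07801, to −1.98 ± 0.06 and gap20, RMQ01365, to −1.31 ± 0.20.

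Ribosomal proteins had the highest median of the lists with formaldehyde. Of 36 measured genes 27 rose and 6 fell, the same adjusted over the list alone, with a median of 1.53. Over the 24 of them with all values the camera adjusted p was 1.2e-06. The same list had an adjusted p = 0.100 with an estimated correlation. With only genes read in both dye orientations its adjusted p was 0.165. The array holds 60 genes of this list, a pair of ribosomal protein methyltransferases among them, and non-uniform spots left 36 of them measured, against 59 with such spots kept. Over those 59 the median was 0.798, with 35 rises and 17 falls, an adjusted p of 1.5e-04 and an adjusted p = 0.553 with an estimated correlation. S21P, RMQ12385, stood at 2.75 ± 0.23. Of 20 genes of RNA polymerase and translation factors 13 rose and 3 fell, the same adjusted over the list alone, with an adjusted p of 0.0705. Among them rho, RMQ11529, which ends transcription, rose by 2.44 ± 0.31, initiation factor IF-1, RMQ05961, by 1.74 ± 0.10 and the main sigma factor gene rpoD, RMQ04419, by 1.71 ± 0.24. Of 28 genes of ATP synthase and NADH dehydrogenase 15 rose and 6 fell, and 16 and 7 adjusted over the list alone, with an adjusted p of 0.0572. The delta chain of ATP synthase, RMQ07546, rose by 2.93 ± 0.32 and NADH dehydrogenase chain A, RMQ09630, by 1.60 ± 0.19.

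Chaperones and repair genes moved both ways. Of 36 chaperone and protease genes 13 rose and 9 fell with formaldehyde, the same adjusted over the list alone, with an adjusted p of 0.597. GrpE, RMQ03555, the nucleotide exchange factor of DnaK, rose by 1.48 ± 0.17 and a dnaK gene, RMQ09537, by 1.19 ± 0.22, while another dnaK gene, RMQ06982, fell by 0.68 ± 0.28. GroEL genes RMQ02595 and RMQ11455 stood at 0.02 ± 0.08 and −0.10 ± 0.10 without passing. ClpB genes RMQ07480 and RMQ04095 fell to −0.81 ± 0.31 and −0.42 ± 0.05, and RMQ11887 stood at −0.01 ± 0.15. Of 38 genes of DNA repair 8 rose and 12 fell, the same adjusted over the list alone, with an adjusted p of 0.569. A DNA repair exonuclease, RMQ01352, rose by 1.33 ± 0.22 and a uracil DNA glycosylase, RMQ06758, fell by 1.92 ± 0.45. The recombinase gene recA, RMQ06415, stood at 0.06 ± 0.32 with an adjusted p of 0.655. With non-uniform spots kept, the SOS repressor gene lexA, RMQ07068, fell by 0.47 ± 0.30.

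Among 28 genes of peroxide and thiol defence 6 rose and 12 fell with formaldehyde, the same adjusted over the list alone, and 9 of the falls were at least 2-fold, with an adjusted p of 0.173. The Dps gene, RMQ05258 (contig 1552, 975 to 1499), whose product coats and shields DNA in starved cells, fell by 2.66 ± 0.41. Manganese catalase, RMQ08596, stood at −2.52 ± 0.31, catalase RMQ00267 at −1.48 ± 0.06 and thioredoxin reductase, RMQ09692, at −1.11 ± 0.15. General stress proteins gave 2 falls among 4 genes, and 1 rise and 2 falls adjusted over the list alone, with an adjusted p of 0.882. General stress protein 39, RMQ07731, fell by 2.31 ± 0.13. Of 31 genes of compatible solutes and ion transport 5 rose and 15 fell, the same adjusted over the list alone, with an adjusted p of 0.193. A trehalose-phosphate synthase gene, RMQ12095, fell by 1.79 ± 0.36 while trehalose synthase, RMQ10898, which makes the same sugar from maltose, rose by 1.55 ± 0.33. Efflux genes gave 8 rises and 17 falls among 35, the same adjusted over the list alone, with an adjusted p of 0.114. Multidrug resistance protein A, RMQ06762, fell by 2.06 ± 0.09.

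Motility genes gave 27 rises and 28 falls among 89 with formaldehyde, and 27 and 26 adjusted over the list alone, with an adjusted p of 0.713. The motor gene pomA, RMQ08077, rose by 1.77 ± 0.05, against the deep fall of flgC. Of 11 genes of iron-sulfur clusters and iron, 5 rose and 2 fell, the same adjusted over the list alone, with an adjusted p of 0.219, and bacterioferritin, RMQ07207, an iron store, rose by 1.33 ± 0.45. Of 12 genes of cysteine and methionine metabolism 5 rose and 2 fell, and 4 and 2 adjusted over the list alone, with an adjusted p of 0.231, and the sulfate importer gene cysA, RMQ03947, rose by 1.66 ± 0.34. Mobile elements, the transposase and integrase genes, gave 139 rises and 31 falls among 221, and 140 and 33 adjusted over the list alone. Their median was 0.56 and their adjusted p 2.6e-08, and they had an adjusted p = 0.100 with an estimated correlation. Transposase RMQ08057 rose by 2.98 ± 0.13. Of the measured elements 103 had a probe with a 20-base stretch found in another gene's probe, and 118 had none. Leaving out any 1 replicate kept the count of genes changed by formaldehyde between 3739 and 4220. The p-values measure only the spread between these samples, since the labels do not say whether the replicates were separate chemostat cultures.

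**Figure D1:**
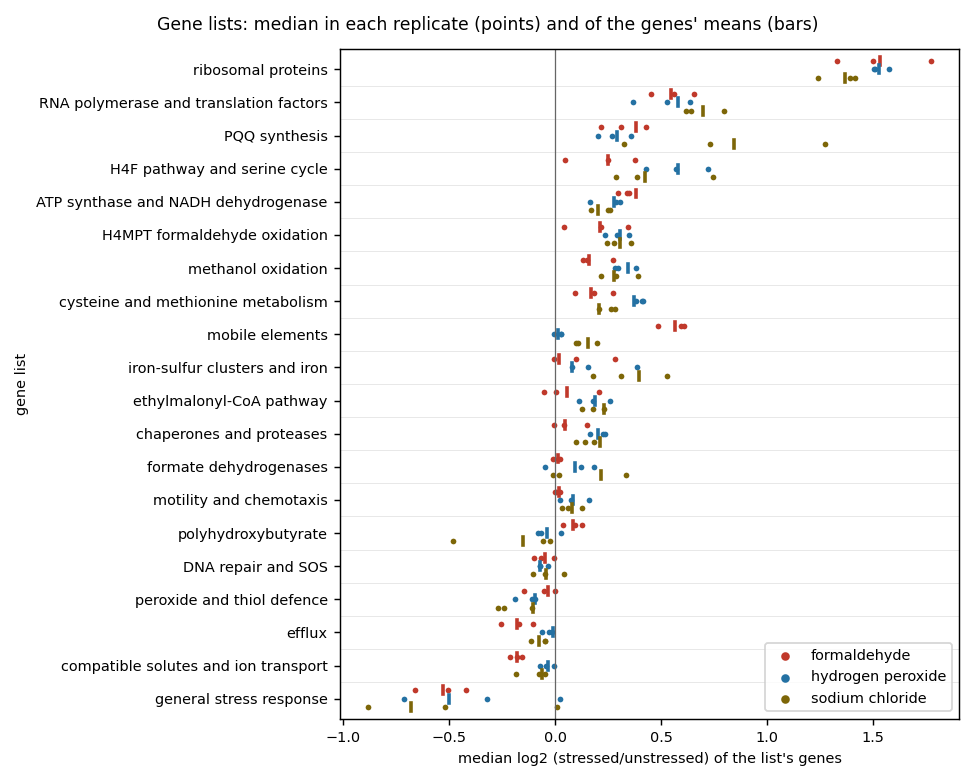
Median log2 ratio of stressed to unstressed signal (horizontal axis) for each of 20 gene lists (vertical axis), with 1 point per biological replicate and a bar at the median of the genes' means, by stressor. Ribosomal proteins lie furthest right, with medians of 1.53, 1.53 and 1.37, and mobile elements part formaldehyde, at 0.56, from sodium chloride, at 0.16, while medians close to 0, such as those of DNA repair, change sign with the processing. With non-uniform spots kept the ribosomal medians were lower, at 0.798, 0.996 and 0.932.

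With hydrogen peroxide 28 of 36 ribosomal protein genes and 15 of 28 genes of ATP synthase and NADH dehydrogenase rose. Both lists passed in camera, with an adjusted p of 1.7e-08 and 0.0286, but had an adjusted p = 0.100 and an adjusted p = 0.623 with an estimated correlation. The repressor genes RMQ09866 and RMQ02230 did not pass, and catalase, peroxiredoxin and Dps genes, whose products defend against peroxide in other bacteria, fell. Of 6272 genes 3706 changed, 1780 up and 1926 down, and 854 changed at least 2-fold, 349 up and 505 down. Under median centring 1913 of 3664 were up, a share of 52.2% where it was 48.0% here. S12P RMQ04459 rose by 4.88 ± 0.19, S1P RMQ01212 by 4.41 ± 0.31 and S12P RMQ00454 by 4.32 ± 0.33. ATP synthase delta chain, RMQ07546 (contig 1281, 4159 to 4725), rose by 3.55 ± 0.07. The export chaperone gene secB, RMQ03221 (contig 1330, 10466 to 11020), rose by 3.03 ± 0.12, the iron-sulfur subunit of ubiquinol-cytochrome c reductase, RMQ02195 (contig 1567, 62887 to 62342), by 3.01 ± 0.24 and a gene annotated as heat resistant agglutinin, RMQ02203 (contig 1526, 21116 to 20256), by 2.85 ± 0.36.

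The deepest fall with hydrogen peroxide was in RMQ12284 (contig 1497, 15979 to 15785), with no described product, at −5.23 ± 0.62, followed by ybiS RMQ00690 at −5.09 ± 1.06. Catalase RMQ10649 stood at −4.45 ± 0.89 with an adjusted p of 1.6e-07, katA RMQ09549 at −3.87 ± 1.04, manganese catalase RMQ08596 at −2.94 ± 0.54 and catalase RMQ00267 at −1.73 ± 0.18. Peroxiredoxin RMQ03709 fell to −4.26 ± 0.18 and Dps RMQ05258 to −3.73 ± 0.72. The large subunit of alkyl hydroperoxide reductase, RMQ00866, fell by 1.33 ± 0.12, and its ratio with formaldehyde was 0.03 ± 0.03. Of 28 genes of peroxide and thiol defence 8 rose and 13 fell, the same adjusted over the list alone, with an adjusted p of 0.0814. Glutathione-dependent formaldehyde dehydrogenase RMQ06757 fell to −3.36 ± 0.44, and an aminomethyltransferase, RMQ04395 (contig 1252, 7486 to 8040), to −3.53 ± 0.63. Topoisomerase I RMQ08276 stood at −4.14 ± 0.58, yciF RMQ10020 at −4.22 ± 0.80, flgC RMQ05513 at −3.85 ± 0.23 and the permease gene RMQ04816 at −3.77 ± 0.46.

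Among the lists of growth with hydrogen peroxide, ribosomal proteins gave 28 rises and 2 falls among 36, the same adjusted over the list alone, with a median of 1.53, an adjusted p of 1.7e-08 and an adjusted p = 0.100 with an estimated correlation. With non-uniform spots kept their median was 0.996, with 49 rises and 3 falls among 59, an adjusted p of 9.9e-16 and an adjusted p = 0.195 with an estimated correlation. RNA polymerase and translation factors gave 11 rises and 3 falls among 20, the same adjusted over the list alone, with an adjusted p of 0.0302 and an adjusted p = 0.623 with an estimated correlation. ATP synthase and NADH dehydrogenase gave 15 and 4 among 28, the same adjusted over the list alone, with an adjusted p of 0.0286 and an adjusted p = 0.623 with an estimated correlation. Release factor RF-2, RMQ06842, rose by 2.15 ± 0.24 and elongation factor EF-P, RMQ06914, by 1.97 ± 0.06. Methanol oxidation gave 17 rises and 5 falls among 26, the same adjusted over the list alone, with an adjusted p of 0.0468 and an adjusted p = 0.623 with an estimated correlation. The methanopterin route gave 14 and 1 among 23, and 15 and 1 adjusted over the list alone, with an adjusted p of 0.0322 and an adjusted p = 0.623 with an estimated correlation. Cofactor gene orf21 RMQ09678 rose by 1.63 ± 0.03 and fae RMQ09682 by 0.35 ± 0.08, the latter lost under median centring at 0.01 and an adjusted p of 0.938. The stressed signal of fae was 15.9 log2 units there, near the top of the range, so the size of its rise is uncertain.

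Of the other lists with hydrogen peroxide, PQQ synthesis gave 3 rises and 0 falls by limma among 7 genes, 3 and 0 at an unadjusted p under 0.05, 2 and 0 adjusted over the list alone, with an adjusted p of 0.173 and pqqE, RMQ08767, at 0.56 ± 0.18. Formate dehydrogenases gave 5 and 5 among 14, the same adjusted over the list alone, with an adjusted p of 0.848, and alpha chain RMQ05881 fell by 2.42 ± 0.24. The serine cycle gave 9 and 3 among 13, and 10 and 3 adjusted over the list alone, with an adjusted p of 0.193, and sga RMQ12088 rose by 1.67 ± 0.47. The ethylmalonyl-CoA pathway gave 7 and 2 among 16, the same adjusted over the list alone, with an adjusted p of 0.275, and pccA RMQ11711 rose by 1.07 ± 0.10. Polyhydroxybutyrate genes gave 3 and 4 among 9, the same adjusted over the list alone, with an adjusted p of 0.882, and the synthase gene RMQ06009 fell by 2.56 ± 0.24. Chaperones gave 18 and 8 among 36, and 18 and 9 adjusted over the list alone, with an adjusted p of 0.155. Here htpG, RMQ09510, rose by 1.05 ± 0.18 and groEL RMQ02595 by 0.74 ± 0.20.

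DNA repair genes gave 8 rises and 9 falls among 38 with hydrogen peroxide, the same adjusted over the list alone, with an adjusted p of 0.785, and recA RMQ06415 stood at 0.23 ± 0.10 without passing. General stress proteins gave 0 rises and 2 falls by limma among 4, the same at an unadjusted p under 0.05, with 0 rises, and adjusted over the list alone, with an adjusted p of 0.795. Compatible solutes gave 6 and 8 among 31, the same adjusted over the list alone, with an adjusted p of 0.785, and trehalose-phosphate synthase RMQ12095 fell by 2.87 ± 0.32. Motility genes gave 36 and 21 among 89, and 38 and 21 adjusted over the list alone, with an adjusted p of 0.0902. The rod gene flgB, RMQ07969, rose by 1.93 ± 0.20, opposite to flgC. Iron-sulfur and iron genes gave 5 and 1 among 11, and 5 and 2 adjusted over the list alone, with an adjusted p of 0.229. Efflux genes gave 8 and 11 among 35, the same adjusted over the list alone, with an adjusted p of 0.713. Cysteine and methionine genes gave 8 and 1 among 12, the same adjusted over the list alone, with an adjusted p of 0.0707. Mobile elements gave 60 and 56 among 221, and 58 and 54 adjusted over the list alone, with an adjusted p of 0.882. Leaving out any 1 replicate gave 2915 to 3741 genes changed by hydrogen peroxide.

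The ratios with sodium chloride correlated at 0.954 with those of hydrogen peroxide across genes, and chorismate mutase rose more than with either other stressor. Of the ribosomal protein genes 27 of 36 rose, and of ATP synthase and NADH dehydrogenase 14 of 28. Both lists passed in camera, with an adjusted p of 1.1e-06 and 0.0458, but had an adjusted p = 0.100 and an adjusted p = 0.623 with an estimated correlation. Of 6272 genes 4193 changed, 2058 up and 2135 down, and 924 changed at least 2-fold, 453 up and 471 down. Under median centring 2175 of 3833 were up, a share of 56.7% where it was 49.1% here. S12P RMQ04459 rose by 4.69 ± 0.33, S1P RMQ01212 by 4.33 ± 0.34 and a subunit annotated as ATP synthase, RMQ08843 (contig 1498, 1600 to 1235), by 3.73 ± 0.60. Chorismate mutase, RMQ04738 (contig 1544, 6588 to 6923), which leads to phenylalanine and tyrosine, rose by 3.55 ± 0.46 with an adjusted p of 2.4e-08. The ferrichrome receptor gene, RMQ02548 (contig 1403, 9630 to 11801), which takes up an iron chelate, rose by 2.97 ± 0.76, and by 2.19 ± 0.70 with formaldehyde and 2.71 ± 0.56 with hydrogen peroxide. Among the falls RMQ08196 stood at −5.86 ± 0.41, RMQ12794 (contig 1556, 20751 to 20578), also without described product, at −5.25 ± 0.68 and ybiS RMQ00690 at −5.18 ± 0.29. The transglycosylase-associated gene RMQ12224 stood at −4.55 ± 0.12, catalase RMQ10649 at −4.37 ± 0.41, Dps RMQ05258 at −3.81 ± 0.05 and formaldehyde dehydrogenase RMQ06757 at −3.64 ± 0.13 (n = 2).

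The list for coping with salt did not pass with sodium chloride. Of 31 genes of compatible solutes and ion transport 5 rose and 12 fell, the same adjusted over the list alone, with an adjusted p of 0.373. Trehalose-phosphate synthases RMQ12095 and RMQ01311 fell to −2.03 ± 0.20 and −1.67 ± 0.42, aquaporin RMQ08943, a water channel, fell by 0.94 ± 0.28, and trehalose synthase RMQ10898 rose by 1.63 ± 0.47. Ribosomal proteins gave 27 rises and 2 falls among 36, the same adjusted over the list alone, with a median of 1.37, an adjusted p of 1.1e-06 and an adjusted p = 0.100 with an estimated correlation, and with only genes read in both orientations an adjusted p of 0.137. With non-uniform spots kept their median was 0.932, with 39 rises and 4 falls among 59, an adjusted p of 1.5e-10 and an adjusted p = 0.325 with an estimated correlation. RNA polymerase and translation factors gave 12 and 3 among 20, the same adjusted over the list alone, with an adjusted p of 0.0302 and an adjusted p = 0.623 with an estimated correlation, and rpoD RMQ04419 rose by 2.24 ± 0.13. ATP synthase and NADH dehydrogenase gave 14 and 3 among 28, the same adjusted over the list alone, with an adjusted p of 0.0458 and an adjusted p = 0.623 with an estimated correlation. The methanopterin route gave 13 and 1 among 23, the same adjusted over the list alone, with an adjusted p of 0.0302 and an adjusted p = 0.623 with an estimated correlation, and fae RMQ09682 rose by 0.31 ± 0.11, lost under median centring at 0.08 and an adjusted p of 0.466. With sodium chloride too the stressed signal of fae, 15.8 log2 units, was near the top of the range, so the size of its rise is uncertain.

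Methanol oxidation gave 16 rises and 5 falls among 26 with sodium chloride, and 17 and 5 adjusted over the list alone, with an adjusted p of 0.0529, and mxaR RMQ04256 rose by 1.21 ± 0.04. PQQ synthesis gave 5 and 0 by limma among 7, 6 and 0 at an unadjusted p under 0.05, and 6 and 0 adjusted over the list alone, with an adjusted p of 0.0619. Formate dehydrogenases gave 6 and 6 among 14, the same adjusted over the list alone, with an adjusted p of 0.882. The serine cycle gave 8 and 1 among 13, and 8 and 2 adjusted over the list alone, with an adjusted p of 0.418, and mtdA RMQ03311 rose by 1.45 ± 0.62. The ethylmalonyl-CoA pathway gave 8 and 2 among 16, the same adjusted over the list alone, with an adjusted p of 0.578. Polyhydroxybutyrate genes gave 3 and 4 among 9, and 4 and 4 adjusted over the list alone, with an adjusted p of 0.886. Chaperones gave 20 and 10 among 36, the same adjusted over the list alone, with an adjusted p of 0.193, and dnaK RMQ09537 rose by 1.85 ± 0.33. Peroxide and thiol defence gave 11 and 13 among 28, the same adjusted over the list alone, with an adjusted p of 0.173.

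DNA repair genes gave 10 rises and 12 falls among 38 with sodium chloride, the same adjusted over the list alone, with an adjusted p of 0.785. General stress proteins gave 0 and 2 by limma among 4, the same at an unadjusted p under 0.05, with 0 rises, and adjusted over the list alone, with an adjusted p of 0.597, and RMQ07731 fell by 2.72 ± 0.68. Motility genes gave 37 and 17 among 89, the same adjusted over the list alone, with an adjusted p of 0.0826, and the chemotaxis kinase homologue pilL, RMQ09416, rose by 2.25 ± 0.21. Iron-sulfur and iron genes gave 6 and 2 among 11, the same adjusted over the list alone, with an adjusted p of 0.193. Efflux genes gave 8 and 13 among 35, the same adjusted over the list alone, with an adjusted p of 0.491, and the sodium-driven pump RMQ02213 fell by 1.34 ± 0.05. Cysteine and methionine genes gave 6 and 1 among 12, and 4 and 1 adjusted over the list alone, with an adjusted p of 0.219. Mobile elements gave 98 and 52 among 221, and 99 and 52 adjusted over the list alone, with an adjusted p of 0.173. Leaving out any 1 replicate gave 3381 to 4213 genes changed by sodium chloride. Across the 60 tests of a list in a stressor, 11 passed with the preset correlation and 0 with an estimated one in limma's camera, where 4 had an unadjusted p under 0.05. Median centring in place of loess ended 7 of the 11 calls and keeping only genes read in both orientations ended 4, while limma's fry, which asks only whether a list moves on balance, passed 53.

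Relative to flask-shaken unstressed cells, which were not compared here with chemostat cells, most changes were shared by the 3 stressors. The S12P gene RMQ04459 and the S1P gene RMQ01212 rose and catalase RMQ10649, Dps RMQ05258 and peroxiredoxin RMQ03709 fell with each of them, and 1320 genes rose and 1398 fell with all 3. At least 2-fold in all 3, 231 rose and 373 fell, and 160 genes were called in opposite directions in some pair of stressors, 1 of them at least 2-fold in both. Across 6272 genes, which are not independent replicates, the mean log2 ratios of formaldehyde and hydrogen peroxide correlated at 0.879 (Spearman 0.805), those of formaldehyde and sodium chloride at 0.905 (0.847) and those of hydrogen peroxide and sodium chloride at 0.954 (0.908). Genes that rose with formaldehyde and also with hydrogen peroxide numbered 1378, where independent calls would give 582, and 1606 rose with both formaldehyde and sodium chloride, where independence would give 673. For hydrogen peroxide and sodium chloride 1590 rose with both, against 584. Falls shared by these pairs numbered 1515, 1637 and 1642, against 691, 766 and 656. The labels do not say whether stressors shared unstressed RNA, which would by itself correlate their ratios. Simulated unchanged stressors that shared it gave a mean correlation near 0.503 for formaldehyde and hydrogen peroxide but a covariance of 0.00565, where the measured covariance was 0.583. For formaldehyde and sodium chloride the simulated and measured covariances were 0.00559 and 0.623, and for hydrogen peroxide and sodium chloride 0.00561 and 0.660. The simulated stressors varied only as replicates do, so they cannot show what a single unstressed pool on all arrays would give.

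**Figure D2:**
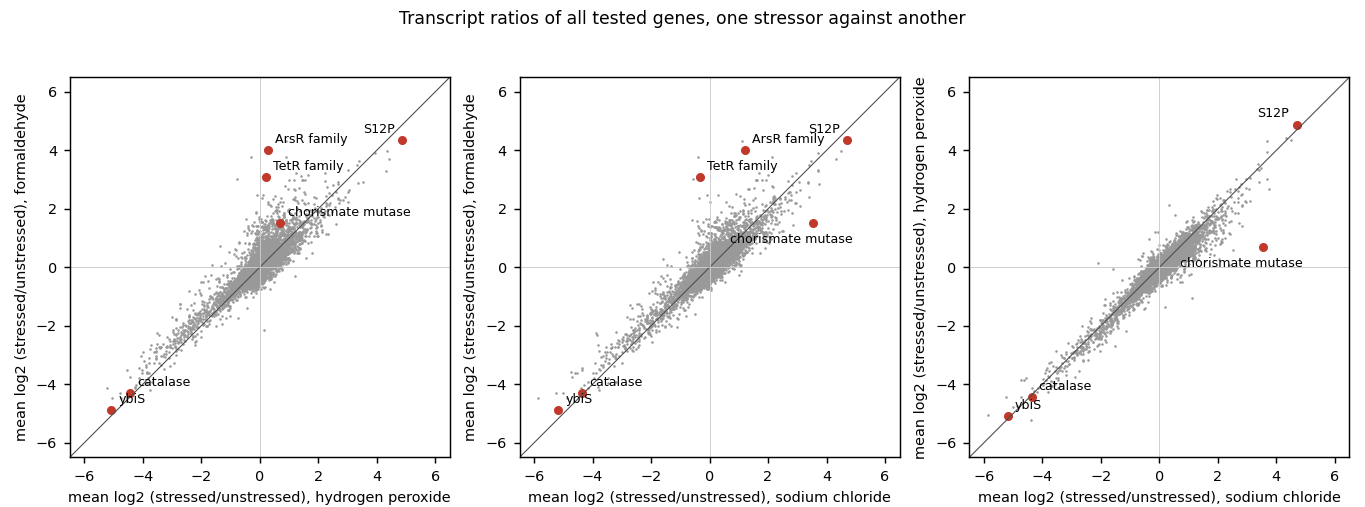
Mean log2 ratio of stressed to unstressed signal of 6272 genes (grey points), with 1 stressor on each axis and the line of equal ratios; named genes are in red. The clouds follow the line, with correlations of 0.879, 0.905 and 0.954, and the ArsR family gene RMQ09866 lies far above it, at 4.01 with formaldehyde and 0.27 with hydrogen peroxide. With sodium chloride the mean ratio of RMQ09866 was more than 2-fold up.

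Transcripts of the ArsR family genes RMQ09866, RMQ09850 and RMQ03334, of the TetR family gene RMQ02230 and of 122 of 221 mobile elements were higher with formaldehyde than with hydrogen peroxide. Those of the nitrogen regulator GlnK, an aspartyl-tRNA synthetase and fructokinase were lower. The difference itself passed in 1436 genes, 916 higher and 520 lower with formaldehyde, and 211 of these differed at least 2-fold, 202 higher and 9 lower. With the scanner's own log ratios 709 of 1401 were higher, a share of 50.6%, where it was 63.8% here. RMQ09866 differed by 3.73 log2 units with an adjusted p of 1.2e-06, RMQ02230 by 2.89 and the ArsR gene RMQ09850 (contig 1553, 26025 to 26381) by 2.29. A further ArsR gene, RMQ03334 (contig 1440, 5983 to 5627), stood at 2.22 ± 0.06 with formaldehyde and 0.29 ± 0.13 with hydrogen peroxide, a difference of 1.93. A DNA integration and recombination gene, RMQ09085 (contig 1450, 11463 to 10480), differed by 1.97, but by 0.66 with an adjusted p of 0.268 in the scanner's log ratios.

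Lower with formaldehyde than with hydrogen peroxide was GlnK, RMQ08730 (contig 1519, 8262 to 8597), which reports nitrogen status to the ammonium channel, at 0.49 ± 0.21 and 1.79 ± 0.10, a difference of −1.29 with an adjusted p of 9.9e-05. Aspartyl-tRNA synthetase, RMQ07982 (contig 1367, 4873 to 5394), stood at 0.33 ± 0.10 and 1.60 ± 0.44, an acetyl-CoA carboxylase subunit, RMQ12448 (contig 1522, 7204 to 8178), which starts fatty acid synthesis, at 1.13 ± 0.30 and 2.32 ± 0.26, and fructokinase, RMQ06674 (contig 1478, 17860 to 16805), at 1.15 ± 0.20 and 2.28 ± 0.22. The gene of the DnaK suppressor protein, RMQ05190 (contig 1532, 25270 to 24854), a regulator that acts with ppGpp on ribosomal promoters, stood at 1.48 ± 0.15 and 2.61 ± 0.12. Of the lists, mobile elements had 122 genes higher and 1 lower with formaldehyde, a median difference of 0.44, a camera adjusted p of 1.6e-19 and an adjusted p = 0.0173 with an estimated correlation. Against the mean of both other stressors their median difference was 0.770 where a 20-base stretch was shared with another gene's probe and 0.163 where none was. Ribosomal proteins had 4 higher and 8 lower among 36, a median difference of −0.03 and an adjusted p of 0.523. With non-uniform spots kept they had 3 higher and 26 lower among 59, a median difference of −0.35, an adjusted p of 1.6e-05 and an adjusted p = 0.749 with an estimated correlation. Chaperones and proteases then had 2 higher and 16 lower among 48 and a camera adjusted p of 3.2e-04, where it was 0.103 without such spots. With an estimated correlation they had an adjusted p = 0.749. The serine cycle had 0 higher and 3 lower by limma, 0 and 6 at an unadjusted p under 0.05, a median difference of −0.43, an adjusted p of 0.0497 and an adjusted p = 0.860 with an estimated correlation. Without hydrogen peroxide replicate 1 the count of differing genes was 858, and without hydrogen peroxide replicate 3 it was 826.

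Against sodium chloride, formaldehyde was again marked by these ArsR and TetR family genes, and by a smaller fall of the aminomethyltransferase gene. The difference passed in 999 genes, 595 higher and 404 lower with formaldehyde, and 124 differed at least 2-fold, 109 higher and 15 lower. With the scanner's log ratios 454 of 871 were higher, a share of 52.1%, and with all 18 arrays 717 of 1362, a share of 52.6%, where it was 59.6% here. RMQ02230 differed by 3.42 log2 units with an adjusted p of 1.2e-06, RMQ09866 by 2.81, RMQ09850 by 2.76, RMQ03334 by 2.20 and aminomethyltransferase RMQ04395 by 1.62. The mean ratio of RMQ09866 with sodium chloride was itself more than 2-fold up, so for this gene the stressors differed in the size of the ratio, not its direction. Chorismate mutase RMQ04738 was lower with formaldehyde, at 1.51 ± 0.32 and 3.55 ± 0.46, a difference of −2.05 with an adjusted p of 1.8e-04. The transporter gene drrA, RMQ06184 (contig 1479, 5169 to 4246), stood at 1.44 ± 0.37 and 2.84 ± 0.17, a glutamyl-tRNA synthetase, RMQ09511 (contig 1548, 6007 to 5105), at 1.24 ± 0.20 and 2.51 ± 0.23, and the bacitracin resistance gene RMQ05817 (contig 1519, 22971 to 23819), whose product recycles the lipid carrier of the cell wall, at 1.23 ± 0.35 and 2.47 ± 0.15. The chemotaxis response regulator gene cheY, RMQ07985 (contig 1367, 1962 to 1582), stood at 0.86 ± 0.14 and 1.95 ± 0.39. Mobile elements had 100 genes higher and 2 lower, a median difference of 0.34, an adjusted p of 1.5e-18 and an adjusted p = 0.0173 with an estimated correlation. Motility genes had 1 higher and 11 lower, with a median difference of −0.14, an adjusted p of 0.00212 and an adjusted p = 0.860 with an estimated correlation. With non-uniform spots kept, ribosomal proteins had 4 higher and 20 lower among 59 and a camera adjusted p of 0.00777, where it was 0.888 without them. Chaperones and proteases then had 1 higher and 16 lower among 48 and a camera adjusted p of 3.1e-04, where it was 0.0915. Both had an adjusted p = 0.749 with an estimated correlation. The count of 999 fell to 542 without formaldehyde replicate 2, to 626 without sodium chloride replicate 2 and to 559 without sodium chloride replicate 3.

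Hydrogen peroxide and sodium chloride differed least. An osmotically inducible protein of the OsmC family, which reduces organic peroxides, and GlnK were higher with hydrogen peroxide, and chorismate mutase, yljA and glutamyl-tRNA synthetase were higher with sodium chloride. The difference passed in 287 genes, 53 higher and 234 lower with hydrogen peroxide, and 41 differed at least 2-fold, 9 higher and 32 lower. OsmC, RMQ00751 (contig 1416, 2508 to 2086), stood at 0.98 ± 0.39 with hydrogen peroxide and −0.34 ± 0.09 with sodium chloride, a difference of 1.32 with an adjusted p of 0.00351. GlnK RMQ08730 differed by 1.25, a resolvase, RMQ03923 (contig 1501, 12979 to 12359), by 1.25, a histidine kinase, RMQ06700 (contig 1484, 345 to 1451), by 1.00 and a UTP-glucose-1-phosphate uridylyltransferase, RMQ07549 (contig 1131, 959 to 1879), by 0.82. The gene yljA, RMQ00582 (contig 1552, 36473 to 37093), next to a clpA gene whose protease its homologues steer, stood at −1.04 ± 0.07 (n = 2) with hydrogen peroxide and 1.11 ± 0.34 (n = 2) with sodium chloride. Chorismate mutase differed by −2.85 and glutamyl-tRNA synthetase RMQ09511 by −1.90. The GntR family regulator RMQ10314 (contig 1566, 38831 to 38142) and the LuxR family regulator RMQ10088 (contig 1561, 16616 to 17371) differed by −1.34 and −1.28. Mobile elements had 0 higher and 19 lower by limma, 1 and 55 at an unadjusted p under 0.05, with a median difference of −0.12, an adjusted p of 0.00251 and an adjusted p = 0.705 with an estimated correlation. The count of 287 fell to 133 without hydrogen peroxide replicate 1, to 146 without hydrogen peroxide replicate 3 and to 123 without sodium chloride replicate 2.

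**Figure D3:**
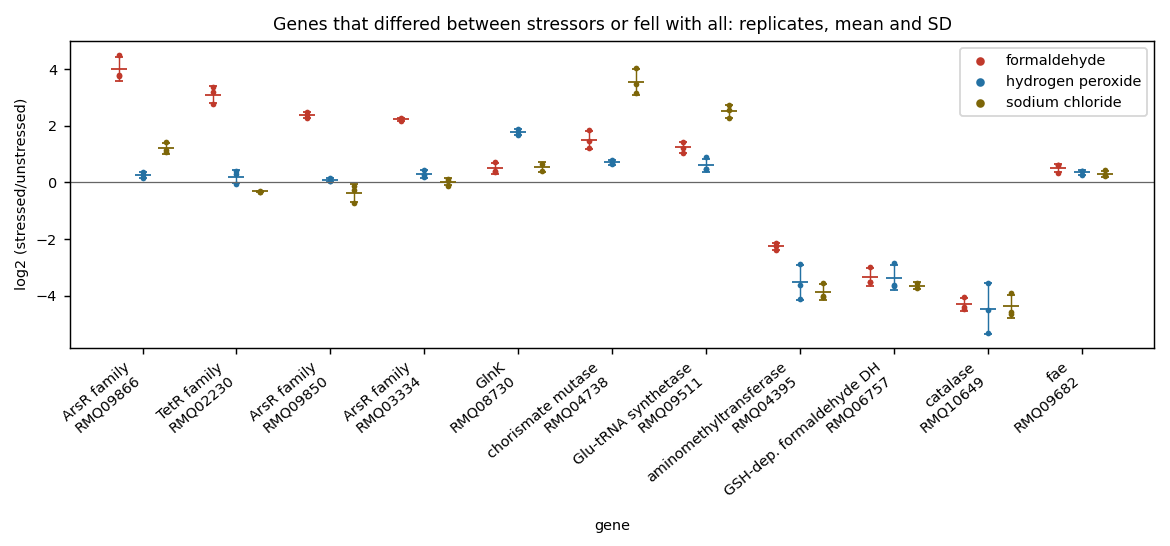
Log2 ratio of stressed to unstressed signal (vertical axis) of 11 genes (horizontal axis), with 1 point per biological replicate and the mean with its SD, by stressor. ArsR family genes RMQ09866, RMQ09850 and RMQ03334 stand at 4.01, 2.38 and 2.22 with formaldehyde and at 0.27, 0.09 and 0.29 with hydrogen peroxide, while catalase RMQ10649 lies at −4.30, −4.45 and −4.37. The ratios of fae RMQ09682 are 0.52, 0.35 and 0.31, calls lost under median centring. Signals of fae lay near the top of the range, so the sizes of its rises are uncertain.

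A single test across the 3 stressors asked which genes responded unequally. The regulators RMQ09866, RMQ02230, RMQ09850 and RMQ03334, chorismate mutase and GlnK were among 1440 genes whose 3 mean ratios differed by limma's moderated F test. That count fell to 928 without formaldehyde replicate 2 and to 907 without hydrogen peroxide replicate 3. Each stressor was extracted from the scans on a day of its own, so that differences between stressors and between extraction days cannot be told apart.

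Ribosomal protein genes did not move as a block. In a long cluster on contig 1333 ratios were near 0 or negative with formaldehyde, along another on contig 1481 they stepped down, and the largest rises lay elsewhere, in genes such as S12P RMQ04459, S1P RMQ01212 and L28P RMQ05738, while another S1P entry, RMQ10522 (contig 310), stood at −0.20. These positions were chosen after the values were seen, and the values below keep non-uniform spots, without which most genes on these 2 contigs have no value. On contig 1333, 11 genes from S10P to S17P had a median of −0.38 with formaldehyde, 0.28 with hydrogen peroxide and 0.17 with sodium chloride. All 11 were lower with formaldehyde than with hydrogen peroxide, and 9 were lower than with sodium chloride, by limma at the same threshold. L16P, RMQ07410 (4158 to 3748), was the lowest, at −1.04 ± 0.17 with formaldehyde. On contig 1481 the first ribosomal protein gene in the direction of transcription, L14P RMQ09269 (10883 to 10518), stood at 1.5 ± 0.33, followed by L24P RMQ00944 at 1.21 ± 0.33, L5P RMQ09268 at 0.72 ± 0.29, S14P RMQ00946 at −0.04 ± 0.26 and S8P RMQ09267 at −0.71 ± 0.29. The same genes fell from 1.97 to 0.28 with hydrogen peroxide and from 2.08 to 0.15 with sodium chloride. Further along, S13P RMQ09257 (4130 to 3666) stood at 2.07 ± 0.22, S11P RMQ05624 at 0.88 ± 0.36 and L17P RMQ05621 at −0.01 ± 0.13 with formaldehyde.

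**Figure D4:**
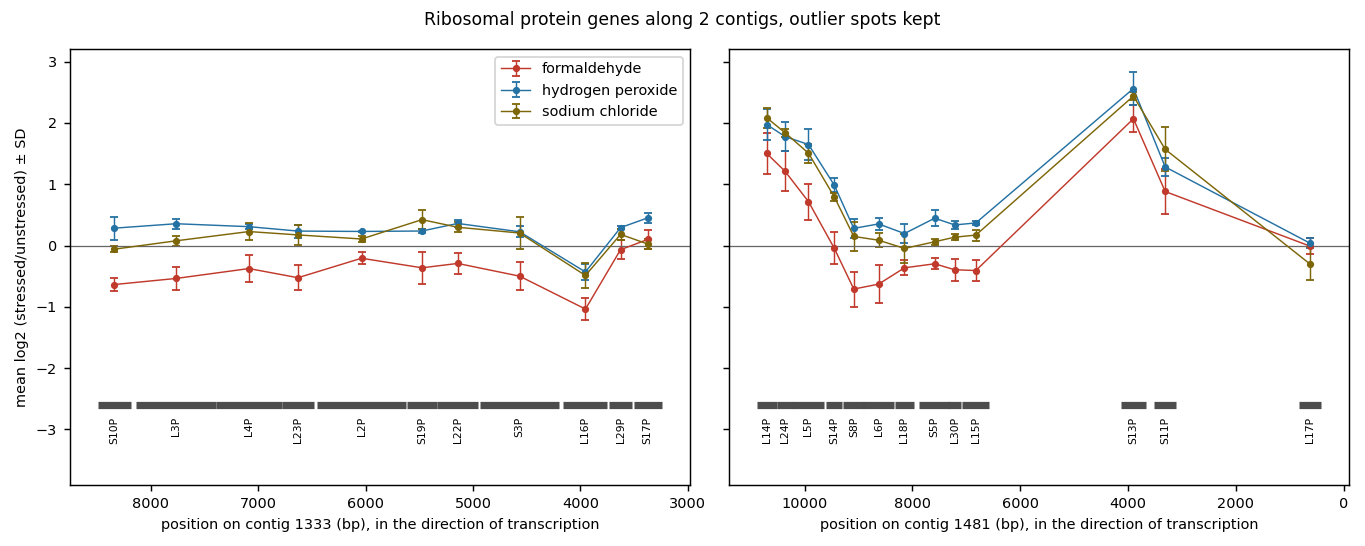
Mean log2 ratio of stressed to unstressed signal ± SD over 3 replicates (vertical axis) of ribosomal protein genes along contigs 1333 and 1481 (horizontal axes, bp, drawn in the direction of transcription), by stressor, with non-uniform spots kept and gene extents as dark bars. From L14P to S8P the ratios step down from 1.5 to −0.71 with formaldehyde, and on contig 1333 formaldehyde lies below hydrogen peroxide at all 11 genes.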

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

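The tests of extraction day, of elements without a shared stretch against lists matched to them and of sign patterns in single stressors were chosen after the results were seen; those of groupings for pairs and for all 3 stressors, dim signals, near-identical copies and a single replicate were set before their values were seen.

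Differences between stressors were found in 1436 genes for formaldehyde and hydrogen peroxide, 999 for formaldehyde and sodium chloride, 287 for hydrogen peroxide and sodium chloride, and 1440 for all 3 at once. For the last, 100 of 280 possible groupings of the 9 replicates were examined, and 1 of them, the real one, gave as many genes. The highest other gave 769. That share is under 0.05, which argues against chance in how the replicates fall into groups. It does not exclude chance, since the remaining groupings were not examined. For the pairs only 10 groupings exist, too few to reach a share under 0.05, and the highest other counts were 0, 0 and 1. For single stressors only 4 patterns of sign exist, too few as well: formaldehyde had 4302 genes against a highest other of 6, hydrogen peroxide 3706 against 46 and sodium chloride 4193 against 155. Differences between stressors stay confounded with the day of extraction.

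Mobile elements were higher with formaldehyde than with either other stressor, with an adjusted p of 0.0173 for each with an estimated correlation and a median difference of 0.392 from the mean of the others. Lists of other genes matched for signal gave medians up to 0.0885, which argues against dim signals, and without formaldehyde replicate 3 the difference was 0.360, which argues against that replicate as its source. Near-identical copies go with the pattern: elements without a stretch shared with a probe of another gene differed by 0.163 and those with one by 0.770, so rising copies read by several probes may account for part of the count. Whether copies account for all of it stays open. Of the 118 elements without a shared stretch 81 lay above 0, and their median lay above the highest of 1000 lists matched to them on signal, 0.0811. The split compared probes with probes only, so a probe without a shared stretch may still read a near-identical copy. The day of extraction cannot be told apart from the stressor, since 0 days held arrays of more than 1 stressor. A rise of transposition genes under formaldehyde stays an open hypothesis.

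Of 24 checks of array quality within the 6 arrays of a stressor, 4 found an array far from the others, where chance flags about 1 in 20. The non-swapped array of formaldehyde replicate 1 had 97.7% of red spots well above background, where the others had 98.3% to 98.7%. The non-swapped array of formaldehyde replicate 3 had 54.0% of its spots marked non-uniform, where the others had 9.25% to 18.9%. The non-swapped array of sodium chloride replicate 1 had 99.1% of red spots well above background, where the others had 98.0% to 98.3%, and an SD of log2 ratios of 0.727, where the others had 0.840 to 0.885. Outside the tests, 9 of the 11 oligonucleotides without a gene were well above background at most of their spots in both channels.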

How the results depend on the processing

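The fit tested with treat, the array of formaldehyde replicate 3 left out and genes read in both orientations were tests added after the results were seen; the others were planned.

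The counts of genes changed by a single stressor lay within 1.5 times of the reported count in 16 of 18 alternatives for each stressor. The exceptions were built to ask for more: requiring at least 2-fold left 916, 854 and 924 genes for formaldehyde, hydrogen peroxide and sodium chloride, and treat against a 2-fold change left 588, 521 and 585. For the differences, requiring 2-fold left 211 genes between formaldehyde and hydrogen peroxide, 124 between formaldehyde and sodium chloride, 41 between hydrogen peroxide and sodium chloride and 251 among all 3, and treat left 41, 19 and 2 for the pairs. The count between hydrogen peroxide and sodium chloride moved most, to 183 with the scanner's log ratios and with the series table, 527 with scaling between arrays and 504 with all 18 arrays; the cause was not tested. Scaling also gave 2162 genes between formaldehyde and hydrogen peroxide, and the cause was not tested. Between formaldehyde and sodium chloride 661 genes were left among those read in both orientations, where fewer genes were tested, and 655 with only these stressors in the fit, where fewer samples gave the spread. The correlation between formaldehyde and hydrogen peroxide was 0.851 with the scanner's log ratios, where the cause was not tested.

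Leaving out 1 replicate in turn gave 3739 to 4220 genes for formaldehyde, 2915 to 3741 for hydrogen peroxide and 3381 to 4213 for sodium chloride. It gave 826 to 1642 between formaldehyde and hydrogen peroxide, lowest at 858 and 826 without hydrogen peroxide replicates 1 and 3. Between formaldehyde and sodium chloride it gave 542 to 1398, with 542 without formaldehyde replicate 2 and 626 and 559 without sodium chloride replicates 2 and 3. Between hydrogen peroxide and sodium chloride it gave 123 to 321, with 133 and 146 without hydrogen peroxide replicates 1 and 3 and 123 without sodium chloride replicate 2. Among all 3 it gave 907 to 1707, with 928 without formaldehyde replicate 2 and 907 without hydrogen peroxide replicate 3. The correlations stayed at 0.867 to 0.881, 0.887 to 0.914 and 0.944 to 0.955.

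Of 6542 comparisons of 348 values of named genes, 6487 kept direction and side of the threshold, 25 lost a call, 24 gained one and 6 reversed. The reversals were pqqA RMQ15762 with formaldehyde, at −0.030 under median centring, fdh2B RMQ12670 with its brightest probe alone, at −0.52, −0.52 and −0.64 for formaldehyde, hydrogen peroxide and sodium chloride, and mxaF RMQ05966 under median centring, at −0.28 with formaldehyde and −0.32 with hydrogen peroxide. The last pair is void, since mxaF's unstressed signal was saturated there, and no change is read from it. The probes of fdh2B differ in sign, pqqA is among the brightest genes, and the cause was not tested further. Of 1182 comparisons of 60 list results, 1121 kept their side, 28 lost a call, 33 gained one and 0 of limma's list calls reversed. Median centring ended 7 of the 11 list calls, those of methanol oxidation with hydrogen peroxide and of the methanopterin route, RNA polymerase and translation factors, and ATP synthase with NADH dehydrogenase with hydrogen peroxide and sodium chloride, at an adjusted p of 0.0676 to 0.181. Genes read in both orientations ended 4, of ribosomal proteins with formaldehyde and sodium chloride and of ATP synthase with NADH dehydrogenase with hydrogen peroxide and sodium chloride; fewer genes were tested there. With an estimated correlation 0 of the 11 list calls passed in camera, where 4 of 60 tests had an unadjusted p under 0.05, while fry passed 53. Replicate numbers did not pair the samples across stressors, with correlations of residuals from −0.352 to 0.369, and a replicate block kept every count within 1.5 times. With non-uniform spots kept, 4204 of 4302 calls for formaldehyde, 3620 of 3706 for hydrogen peroxide and 4073 of 4193 for sodium chloride were shared. Dim signal limited the ratios of 30, 46 and 18 genes in both channels and of 28, 44 and 10 in 1 channel.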

Other observations

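The tests of shared unstressed RNA and of dye bias reported here were chosen after the results were seen, and the genes and families named were picked after their values were seen; the tests along neighbouring genes, of bright spots and of exchanged labels were set before their values were known.

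Formaldehyde set 94 genes at least 2-fold above their level with both other stressors, and 0 at least 2-fold below by limma's threshold, 0 also at an unadjusted p under 0.05. Of the 94, 37 were mobile elements, 8 were regulators and 39 had no described product, and 76 had risen past the threshold with formaldehyde itself. They were spread over 70 contigs. Of those without a described function, the furthest above both other stressors were RMQ08797 (contig 1468, 19384 to 19196), at 3.77 with formaldehyde and −0.31 and −0.40 with hydrogen peroxide and sodium chloride, and RMQ03949 (contig 1240, 1500 to 1835), at 3.01, −0.76 and −0.57. An iron-sulfur protein of a membrane-bound aldehyde dehydrogenase, RMQ05353 (contig 1468, 6171 to 6797), stood at 1.16, 0.10 and 0.05, and FMN reductase RMQ12434 at 1.46, 0.44 and 0.44. Others rank here because they fell less with formaldehyde, such as the elongation factor gene greB, RMQ09049, at −0.82, −2.44 and −1.98.

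Regulator families were counted without a test between them. Of 7 ArsR family genes tested, 4 rose and 2 fell with formaldehyde, while 1 rose and 4 fell with hydrogen peroxide and 1 rose and 5 fell with sodium chloride, and 4 were higher with formaldehyde than with each other stressor. In 2 places an ArsR gene lies back to back with a gene for the arsenic resistance protein ArsH, an NADPH-dependent FMN reductase in other bacteria. On contig 1371, ArsR RMQ03388 (8653 to 9012) stood at 1.26, −0.56 and −0.29 and ArsH RMQ03389 (8605 to 7856) at 1.35, 0.23 and 0.26. On contig 1553, ArsR RMQ09850 (26025 to 26381) rose by 2.38 with formaldehyde while ArsH RMQ09849 (25974 to 25231) stood at −0.31, −1.89 and −1.66, so both genes of each pair were at least 2-fold higher with formaldehyde than with the others. Of 15 TetR family genes 4 were higher and 2 lower with formaldehyde than with hydrogen peroxide, of 20 LysR family genes 3 and 2, of 17 AraC family genes 3 and 2, of 13 GntR family genes 2 and 1, and of 17 sigma factors 1 and 3. Of 4 LuxR family genes 2 were higher, and of 9 MarR family genes 0 differed by limma, 2 at an unadjusted p under 0.05. Against sodium chloride, TetR genes gave 4 higher and 1 lower, AraC genes 2 and 1, GntR genes 0 and 1 and sigma factors 0 and 3. LuxR genes gave 1 and 0, MarR genes 0 and 1, and LysR genes 0 and 0 by limma, 3 and 3 at an unadjusted p under 0.05.

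The response shared by all stressors was weighed against technical sources. Unstressed RNA common to the stressors would correlate their ratios, but the lowest covariance of any pair, that of formaldehyde and hydrogen peroxide, was 0.583 where simulated sharing gave at most 0.00672 in any pair. That argues against shared replicate noise of unstressed samples. A deviation common to every unstressed sample, as from a single pool, would not appear in the simulation and stays open. Dye bias would turn its sign with the dyes, but the orientations of a replicate correlated at 0.926 or more. If stressed and unstressed labels had been exchanged on every array, the channels called unstressed would hold 3 different stresses, but in genes that differ among stressors the stressor means spread 2.17 times as much in the channels called stressed, against 0.981 in the other genes tested, which argues against it as far as unstressed samples resembled each other. Also open is whether a common stress response or the state of the flask-shaken unstressed cells, for which no chemostat sample was analysed here, sets these shared ratios.

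Genes of the ribosomal protein list changed unequally, 29 of 59 beyond 2-fold and 30 within it with non-uniform spots kept. Those within it include the pair of ribosomal protein methyltransferases. Ratios compressed at bright spots are argued against, since 16.5% of 557 other genes in the same range of signal were beyond 2-fold. The step down along contig 1481 led to the hypothesis that rises fade along a run of genes. In 255 neighbouring pairs on the same strand with a gene at least 2-fold up, the upstream gene was the higher in 60.8% (permutation p of 0.0146, two-sided, over 201 runs), and in 275 pairs with a gene at least 2-fold down it was the lower in 46.5% (permutation p of 0.0703). Over all 2539 neighbouring pairs, which include those with strong rises, the upstream gene was the higher in 52.3% (permutation p of 0.0146). The other pairs were not tested alone, so whether the upstream excess is confined to pairs with strong rises stays open. The first set holds the ribosomal pairs that prompted the question, and without them the share was 59.7% of 248 pairs (permutation p of 0.0277), short of the 60% set beforehand, so a fading of rises stays open. The value for falls argues against the same there.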
